A study of Mus musculus with 32 samples.

How the data were processed

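Bulk RNA-seq was performed on 32 mice in which the endogenous Apoe gene had been replaced by human APOE3 or APOE4 (targeted replacement on a C57BL/6 background). Per the labels' protocols, a craniotomy of 4.5 mm was opened over the left parietal cortex. TBI animals then received 1 controlled cortical impact (a metal tip of 3 mm driven 1 mm deep), and sham animals received anaesthesia and craniotomy without impact. Cortex and hippocampus at the injury site were collected together at day 14, after removal of subcortical tissue, and RNA was purified with the RNeasy kit. The submitters' processing notes name Subread 1.5.0, edgeR 3.14.0 and the mouse genome build mm10. The role of each tool, the gene annotation, the strand setting and the handling of reads from human APOE were not given in the sources used here.

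The authors deposited 1 table of raw read counts per gene for all 32 libraries, beside their own log2 coefficient for TBI against sham and its p-value, per the file headers. The counts were whole numbers and not normalised. The table held 5582 genes, of which the authors' deposited table lists 2983 with a positive and 2599 with a negative log2 coefficient. The highest p-value in the authors' deposited table was 0.0503, and 6 rows lay above 0.05. The listed genes were therefore selected on the injury contrast in the same animals. Injury calls and false discovery rates over this table are not independent of that selection. Genotype and interaction tests were not selected on, but cover the listed genes only. Genes whose injury responses cancel between the genotypes tend to be missing from the list. Other genes were not analysed here. A total of 13 gene symbols that a spreadsheet had turned into dates were restored from their NCBI gene identifiers, and 5557 identifiers were matched to a RefSeq gene table of assembly GRCm38.p6 for coordinates.

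Column totals over the listed genes ran from 2262242 to 8606717 counts per library. These are sums over a selected gene list and not library depths. They fell into 16 shallow libraries of at most 3595246 counts and 16 deep libraries of at least 4648345 counts, with both kinds in each of the 4 groups. The median gene had 244 counts per library, and the biological coefficient of variation was 11.5%. The gene with the largest share of a library took 2.40% of its counts.

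Groups were taken from the labels. The library E2073 was titled as sham and described as TBI, and the library F1372 was titled as APOE3 and described as APOE4. Both were left out of the comparisons, which leaves 30 animals. Animal numbers separate the libraries, so replicates were taken as separate animals.

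Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-tests), which kept 5371 genes and dropped 211 with low counts. Genotype and the letter M or F in the animal titles were covariates. The labels do not spell out this letter. TBI was compared with sham over all 30 animals and within each genotype, and APOE4 was compared with APOE3 over both injury states. The injury by genotype interaction was a term of its own model. Adjusted p-values are Benjamini-Hochberg values from edgeR, with a threshold of 0.05. Log2 differences carry the standard error of the fit, and levels are TMM-scaled CPM over the listed genes, as mean ± SD over animals. TMM assumes that changes balance over the listed genes, so directions are relative to the list. Levels in log2 CPM used a prior count of 1.

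The direction of 38 gene lists was tested by Fisher's exact test (2-sided) of higher against lower log2 differences among list members against the other tested genes. Benjamini-Hochberg adjustment ran over the 31 lists with at least 5 tested genes. List members absent from the authors' table or dropped for low counts were not tested, so shares are of tested members only. Each list median was placed among those of 10000 random lists matched on mean expression. Genes are not independent replicates, so a list p describes the table and not the spread between animals. Lists in the other comparisons were tested with camera (preset correlation 0.01, then an estimated correlation) and fry from limma 3.58.1.

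Named genes followed a rule. Among genes past the threshold with an average log2 CPM of at least 0, the 10 largest rises, the 10 largest falls, and the 5 rises and 5 falls with the smallest p could be named. Trem2, Tyrobp and Apoe were always named, and up to 4 members per list with the largest change. Groups, covariates, the tests of the study's comparisons, gene lists and this rule were fixed before the data were examined. The comparison of the title letters, the set tests outside the injury comparison and several alternatives were added later.

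The alternatives were DESeq2 1.42.0 with its size factors, limma-voom, total-count scaling, no filter on low counts and other thresholds. Further alternatives were both placements of the disputed libraries, no covariates, the depth class as a covariate, each depth class alone and leaving out each animal. Without covariates, the genotype and letter comparisons had no injury term either. The scripts were tested on simulated counts for 5371 genes with 200 changed genes. For TBI against sham, 92.0% of genes changed 1.5-fold and 98.0% of genes changed 2-fold were recovered, with 14 false calls (6.70% of calls). For APOE4 against APOE3 the shares were 78.0% and 100%, and for the interaction 62.0% and 86.0%. The simulation gave each gene 1 baseline mean and 1 dispersion in all groups. In the data 94.1% of tested genes passed for injury, and spread could differ between groups. Trem2, for example, stood at 76.6 ± 28.3 CPM in APOE4 TBI and 19.6 ± 1.44 in APOE4 sham animals. The shares therefore need not hold for genes that respond to injury.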

Results

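RNA-seq counts were compared between mice carrying human APOE3 or APOE4 at 14 days after controlled cortical impact or sham surgery, in cortex and hippocampus from the injury site. The groups held 8 APOE3 TBI, 7 APOE3 sham, 8 APOE4 TBI and 7 APOE4 sham animals. The table covered 5371 tested genes out of 5582 that the authors had selected on the injury contrast, at 2262242 to 8606717 counts per library over these genes. The series title names Trem2 and Tyrobp as network hubs after injury, so these genes and the human APOE genotype framed the comparisons.

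The first comparison asked how injury changed the tissue across both genotypes. Trem2, a microglial lipid receptor, rose 3.95-fold (log2 difference 1.98 ± 0.13 SE, adjusted p = 4.98e-14), and Tyrobp, its signalling adaptor, rose 3.62-fold (1.86 ± 0.14, adjusted p = 2.92e-12). Levels were 79.0 ± 25.2 CPM after TBI (n = 16) against 19.7 ± 1.57 in sham (n = 14) for Trem2, and 88.6 ± 37.8 against 23.8 ± 3.62 for Tyrobp. For both genes all 16 TBI animals lay above the highest sham. Trem2 (NCBI gene 83433) lies on chromosome 17 from 48346401 to 48352276 and Tyrobp (NCBI gene 22177) on chromosome 7 from 30413782 to 30417582 (GRCm38.p6). Counts assigned to Apoe, a lipid carrier, rose 1.19-fold (0.25 ± 0.06, adjusted p = 0.000479), and 5 of the 16 TBI animals exceeded the highest sham. These animals carry human APOE, so Apoe counts are reads that mapped to the mouse gene.

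**Figure D1:**
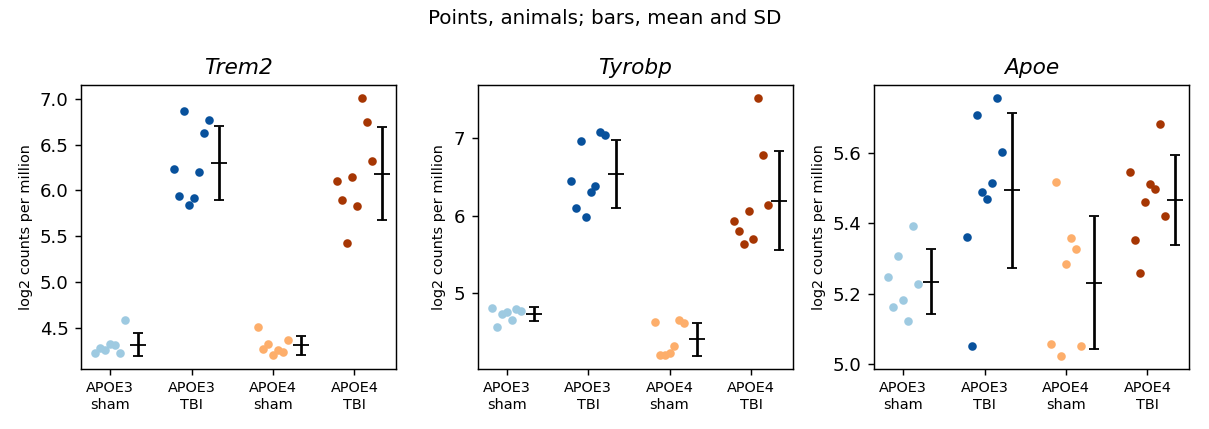
Levels of Trem2, Tyrobp and Apoe in log2 CPM over the listed genes, 1 point per animal in each of the 4 groups of genotype and injury, with group means and SD. All 16 TBI animals lie above the 14 shams for Trem2 and Tyrobp, and the ranges overlap for Apoe.

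Of the 14 tested members of the Trem2-Tyrobp signalling list, 14 rose, with a median log2 difference of 1.35 (Fisher's exact adjusted p = 0.000273). Trem2 and Tyrobp were picked as hubs by the study on these samples, so this list is not independent evidence. Clec7a, a phagocytic lectin receptor, rose most, by 5.64 ± 0.30. Of 25 disease-associated microglia genes, 24 rose with a median of 1.83 (Fisher's exact adjusted p = 9.83e-06), among them Cst7 (5.52), Gpnmb (4.55) and Lyz2 (4.33), whereas Ank fell by 0.11. The 16 homeostatic microglia genes also rose, by a smaller median of 0.72 (Fisher's exact adjusted p = 7.61e-05), with Lag3 at 2.10 and Fcrls at 1.44. All 24 lysosome genes rose (median 0.74, Fisher's exact adjusted p = 1.37e-06), with the proteases Ctss (1.78) and Ctsd (1.57) in front. The 21 genes for Fc receptors and phagocytosis rose (median 1.53, Fisher's exact adjusted p = 8.07e-06), including Cybb (3.88) and Fcgr4 (3.42). The 10 tested genes of infiltrating and border macrophages, out of 17 in the list, rose (median 0.94, Fisher's exact adjusted p = 0.00310), led by Msr1 (3.33) and Ms4a7 (3.20). They did not pass as a list without genes shared between lists (Fisher's exact adjusted p = 0.0838).

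Complement genes rose in 18 of 18 cases (median 1.69, Fisher's exact adjusted p = 2.49e-05). C3, the central complement protein, rose by 7.48 ± 0.42 on the log2 scale, and C4b by 2.47 ± 0.11, the latter with reads that may not be separable from its close copy C4a. The interferon response rose in 34 of 34 genes (median 1.61, Fisher's exact adjusted p = 7.30e-09), with Cxcl10 at 4.73, Zbp1 at 3.09 and Mx1 at 2.78. Antigen presentation by MHC class I rose in 16 of 16 genes (median 1.52, Fisher's exact adjusted p = 7.61e-05), where the near-identical H2-Q6 and H2-Q7 are uncertain, and by MHC class II in 7 of 7 (median 2.15, Fisher's exact adjusted p = 0.0228), led by Cd74 (2.45) and H2-Aa (2.39). Chemokines and cytokines rose in 20 of 20 genes (median 1.91, Fisher's exact adjusted p = 9.83e-06), including Ccl2 (4.91) and Ccl5 (3.98). Ccl2 had 6 counts over all shams, with 10 sham libraries at 0, so the size of its rise is uncertain. Toll-like receptor and NF-kB genes rose in 19 of 19 (median 1.00, Fisher's exact adjusted p = 1.53e-05), led by Tlr2 (3.08) and Tlr1 (1.95).

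**Figure D2:**
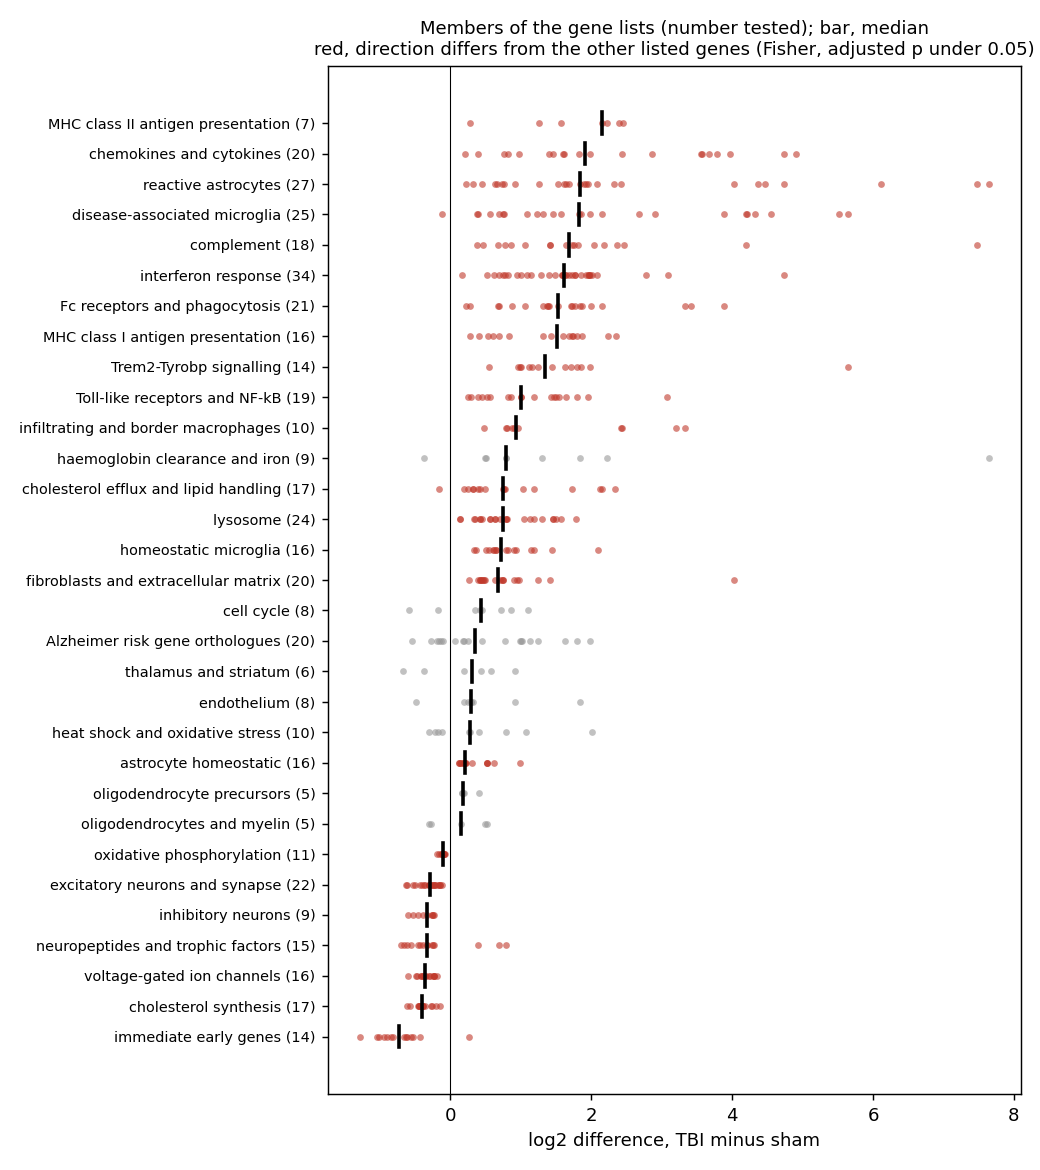
Log2 differences between TBI and sham for the members of each gene list, 1 point per gene, with the list median as a bar and lists past the Fisher test in red. Lists of microglia, complement and antigen presentation lie to the right of 0, and lists of neurons, ion channels and cholesterol synthesis to the left.

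Astrocyte genes followed the immune genes. Gfap, the astrocyte intermediate filament, rose by 2.32 ± 0.10 on the log2 scale (adjusted p = 8.59e-18, shared with C4b as the smallest of the comparison), in 16 of 16 TBI animals above every sham. Of 27 reactive astrocyte genes 26 rose (median 1.84, Fisher's exact adjusted p = 3.75e-07), with the iron-binding protein Lcn2 at 7.65 and the metalloreductase Steap4 at 6.11; Nes stood at 0.22 and did not pass (adjusted p = 0.0922). The 16 homeostatic astrocyte genes rose by a small median of 0.21 (Fisher's exact adjusted p = 7.61e-05), and the water channel Aqp4 by 1.00. Extracellular matrix and fibroblast genes rose in 20 of 20 cases (median 0.67, Fisher's exact adjusted p = 9.83e-06), led by Timp1 (4.02), Lox (1.42) and Col3a1 (1.25). Among 17 genes of cholesterol efflux and lipid handling 16 rose (median 0.75, Fisher's exact adjusted p = 0.000559), with Apoc1 at 2.34, Ch25h at 2.16 and the cholesterol exporter Abca1 at 1.73, and Scarb1 fell by 0.15. Further large rises were Cd5l (6.31), Cxcl5 (5.44), Tgm1 (5.30) and Itgax (4.19). Cd5l had 6 counts over the 14 shams, with 8 sham libraries at 0, so the size of its rise is uncertain. The matrix protease Mmp3 had 0 counts over the 14 shams and 391 over the TBI animals, at least 113-fold higher against a floor of 3 counts over all shams.

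Neuronal genes fell by smaller amounts. In bulk tissue a smaller share of neuronal RNA cannot be told apart from lower levels per cell. The immediate early genes showed the largest falls of any list: 13 of 14 fell (median −0.73, Fisher's exact adjusted p = 0.00104), with Arc at −1.29 ± 0.19, Npas4 at −1.04 and Nr4a1 at −1.01, and Jun rose by 0.27. Animals overlapped in the mean log2 CPM over these genes, taken against the sham mean. It ran from −1.15 to −0.26 in TBI and from −0.96 to 0.60 in sham animals. Of 22 tested genes of excitatory neurons and synapses, out of 29 in the list, 21 fell (median −0.28, Fisher's exact adjusted p = 8.86e-07). They included Homer1 (−0.63) and Nefm (−0.61), and Slc17a6 did not pass (−0.37, adjusted p = 0.107). All 9 tested genes of inhibitory neurons, out of 18 in the list, fell (median −0.33, Fisher's exact adjusted p = 0.00202), led by Pvalb (−0.59) and Gabrd (−0.52). The 16 tested voltage-gated ion channel genes, out of 22 in the list, fell (median −0.35, Fisher's exact adjusted p = 2.06e-05). Scn1a stood at −0.60 and Kcna2 at −0.48. With total-count scaling the medians were −0.19 for excitatory neurons, −0.24 for inhibitory neurons and −0.26 for ion channels, with 0 members higher in each. All 17 cholesterol synthesis genes fell (median −0.40, Fisher's exact adjusted p = 1.20e-05), among them Idi1 (−0.61). Of 15 neuropeptides and trophic factors 12 fell (median −0.33, Fisher's exact adjusted p = 0.0233), including Nptx2 (−0.69) and Bdnf (−0.66), while Igf2 rose by 0.79. The list did not pass without genes shared between lists (Fisher's exact adjusted p = 0.117). The 11 tested genes of oxidative phosphorylation, out of 23 in the list, fell by a median of 0.10 (Fisher's exact adjusted p = 0.000541). But with total-count scaling 2 of the 11 were higher and the median was −0.01. A mean-rank permutation test gave an adjusted p = 0.310. Against random lists matched on mean expression the median lay at percentile 97.42, so these genes fell less than most matched lists. Outside the lists the largest falls were Scn4b (−1.22), Krt80 (−1.19), Rspo1 (−1.18) and Dsp (−1.16), and Lamp5 (−0.95), Rph3a (−0.68) and Osbpl3 (−0.70) had the smallest p among falls.

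Markers of other cells and tissues were few in the table or moved in both directions. Of 5 listed oligodendrocyte and myelin genes 3 rose, as Gsn (0.52), and 2 fell, as Mal (−0.30), with Fisher's exact adjusted p = 1. The 5 precursor genes rose by a median of 0.18 without passing as a list (Fisher's exact adjusted p = 0.0788). In endothelium 7 of 8 genes rose, led by the adhesion molecules Icam1 (1.84) and Vcam1 (0.92), and Cd34 fell by 0.49 (Fisher's exact adjusted p = 0.0861). Thalamus and striatum markers gave 4 rises, 1 fall and Slc17a6 (Fisher's exact adjusted p = 0.737), with Prkcd at 0.92 and Ramp3 at −0.67. In the cell cycle list 5 of 8 genes rose and 2 fell (Fisher's exact adjusted p = 0.324), with Top2a at 1.11 and Cdkn1a at −0.59. Orthologues of Alzheimer risk genes gave 13 rises and 5 falls among 20 (Fisher's exact adjusted p = 0.140), from Ms4a6d (1.80) and Spi1 (1.64) to Sorl1 (−0.54). Haemoglobin clearance and iron genes rose in 8 of 9 cases (Fisher's exact adjusted p = 0.0523), with Hmox1 at 1.30, and heat shock and oxidative stress genes gave 6 rises and 4 falls (Fisher's exact adjusted p = 0.781), with Atf3 at 2.01 and Hsph1 at −0.30. Fewer than 5 members were tested for T and NK cells (3 rose, as Ccl5; Trbc2 fell by 1.07), B cells (2 rose, Igkc at 4.05), neutrophils (2 rose, S100a8 at 3.09), pericytes and smooth muscle (4 rose, Vtn at 0.32) and ependymal cells (4 rose, Foxj1 at 1.13). No choroid plexus or blood genes of the lists were in the table (0 of each). Against random lists matched on mean expression, the medians of Alzheimer risk (percentile 99.95), haemoglobin (99.99) and heat shock genes (99.79) lay high. Endothelium (97.55) and oligodendrocytes (95.2) followed, then thalamus and striatum (76.63), precursors (67.7) and cell cycle (38.11). These percentiles were not adjusted over lists.

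In all 5053 of the 5371 genes passed (2589 higher, 2464 lower); 444 rose and 13 fell at least 2-fold, and 115 rose at least 4-fold. Of 31 lists, 16 were higher and 7 lower by Fisher's exact test. These results cover tested members only, since members without an injury effect tend to be missing from the selected table. Adjusted over the list alone, the counts of rises and falls were those given above for each list. The table was selected by the authors on the same animals, so the 94.1% share that passed is not an independent measure. With total-count scaling all log2 differences shifted by a median of 0.0915 and the split became 2787 higher and 1185 lower (70.2% higher, against 51.2% with TMM).

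**Figure D3:**
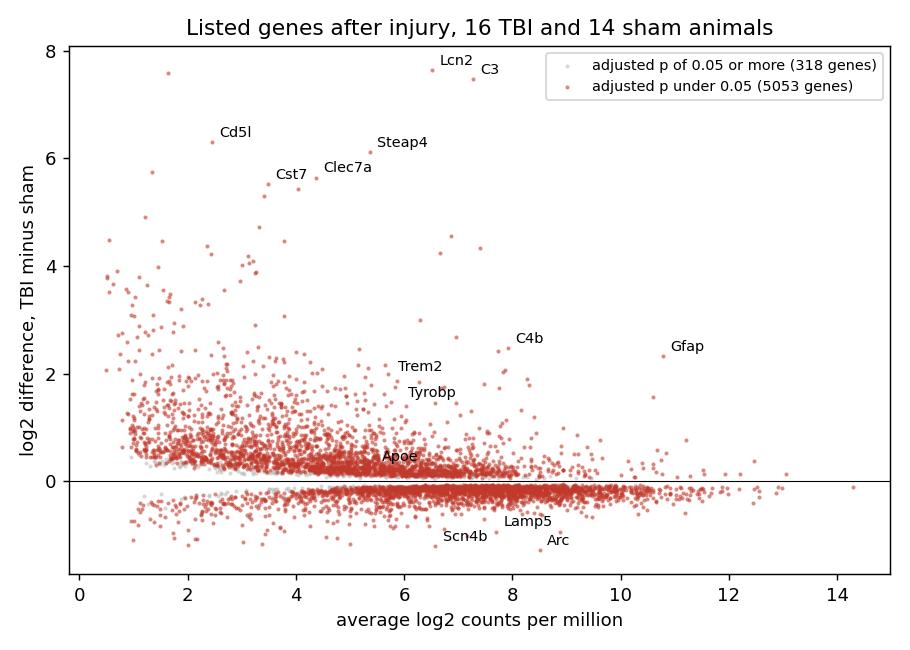
Log2 difference between TBI and sham against average log2 CPM for the 5371 tested genes, 1 point per gene, with named genes labelled. Rises reach 7.65 (Lcn2) and falls reach −1.29 (Arc).

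Injury was next tested within each genotype. In APOE3 mice Trem2 rose 4.13-fold (2.05 ± 0.16, adjusted p = 4.51e-08) and Tyrobp 3.65-fold (1.87 ± 0.16), and in APOE4 mice Trem2 rose 3.69-fold (1.88 ± 0.18, adjusted p = 2.16e-06) and Tyrobp 3.49-fold (1.80 ± 0.22). Lcn2, C3, Cd5l, Clec7a and Steap4 were among the largest rises in both, with C3 at 7.17 and 7.81. Among falls, Scn4b (−1.57), Arc (−1.46), Syt2 (−1.30) and Vamp1 (−0.79) were named in APOE3, and Mylk3 (−1.24), Dsp (−1.16), Arc (−1.14) and Snap25 (−0.40) in APOE4. Apoe counts rose by 0.27 ± 0.09 in APOE3 (adjusted p = 0.0131) and by 0.22 ± 0.09 in APOE4 (adjusted p = 0.0386). The Apoe call in APOE3 was lost in the shallow libraries alone (0.25, adjusted p = 0.193). That in APOE4 was lost with DESeq2 (0.20, adjusted p = 0.055), with placement of the disputed libraries by title (0.07, adjusted p = 0.648), and in the shallow (0.28, adjusted p = 0.111) and deep libraries alone (0.17, adjusted p = 0.312). In APOE3, 3799 genes passed (1938 higher, 1861 lower), and in APOE4, 3287 (1739 higher, 1548 lower). Of these, 2698 passed in both, all in the same direction, on a table selected for a shared injury effect. Log2 differences correlated across genes at r = 0.960, where genes are not independent replicates.

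**Figure D4:**
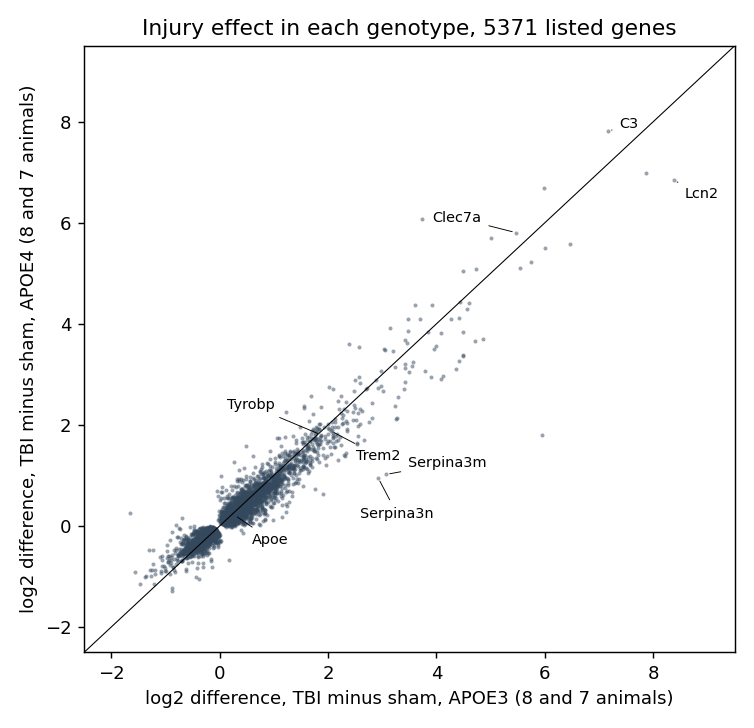
Log2 difference between TBI and sham in APOE3 mice (x axis) against that in APOE4 mice (y axis), 1 point per tested gene. 5350 of 5371 genes have the same sign in both, and Serpina3n and Serpina3m lie below the diagonal.

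The interaction asked whether injury acted differently in the genotypes. The protease inhibitor gene Serpina3n had the smallest p: its rise was smaller in APOE4 by 1.93 ± 0.42 on the log2 scale, with an adjusted p = 0.397. Serpina3n went from 54.6 ± 11.7 to 413 ± 163 CPM in APOE3 (n = 7 and 8) and from 223 ± 78.4 to 500 ± 432 in APOE4 (n = 7 and 8). The interaction was −0.16 ± 0.25 for Trem2, −0.05 ± 0.29 for Tyrobp and −0.06 ± 0.12 for Apoe, each with an adjusted p = 0.999. No gene passed with edgeR (0 of 5371), nor with DESeq2 (0) or limma-voom (0). The list was selected on the injury effect over both genotypes, so genes with opposite responses tend to be missing from these tests. With edgeR, 99 genes had an unadjusted p under 0.05, where 269 would be expected from the threshold alone. Other splits of the animals between the genotypes gave a median of 181. The median gene's 95% interval spanned ±0.26 log2 units around its interaction. Camera with a preset correlation called reactive astrocytes lower (adjusted p = 0.00105), MHC class I lower and immediate early genes higher (adjusted p = 0.0186 each), and the adjusted p = 0.905 for all 3 with an estimated correlation, and 0.941 with fry.

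The genotypes were compared over both injury states. Serpina3m, a protease inhibitor gene of the Serpina3 cluster on chromosome 12, was 9.23-fold higher in APOE4 (3.21 ± 0.28, adjusted p = 1.44e-09), at 17.9 ± 16.4 CPM (n = 15) against 2.03 ± 1.89 (n = 15). Its neighbours Serpina3i (1.66 ± 0.39) and Serpina3n (0.99 ± 0.27, adjusted p = 0.0468) were also higher. For Serpina3n the genotypes lay apart mainly in shams (54.6 ± 11.7 CPM in APOE3, 223 ± 78.4 in APOE4). After TBI they overlapped (413 ± 163 and 500 ± 432), though the interaction did not pass. These near-identical family members can share reads and are uncertain. The stress-response transcription factor Atf4 was 1.39-fold higher (0.48 ± 0.04, adjusted p = 1.44e-09), from 87.9 ± 8.97 to 123 ± 13.5 CPM. Nudt3 (0.31 ± 0.03), the RNA-editing enzyme gene Adar (0.28 ± 0.03) and the mitochondrial fusion gene Mfn2 (0.24 ± 0.03) were higher too. The paraoxonase gene Pon2 was lower by −0.55 ± 0.05 (adjusted p = 1.44e-09), as were Ica1 (−0.39), Hrk (−0.37), Pck2 (−0.28) and Nipsnap1 (−0.22). Larger but less precise differences were Vipr2 (0.61), Mid1 (0.58), Enpp6 (0.55) and Cbln2 (0.49) higher, and Pqlc3 (−0.61), Rxfp3 (−0.55), Wnt2 (−0.54) and Thbs4 (−0.45) lower.

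**Figure D5:**
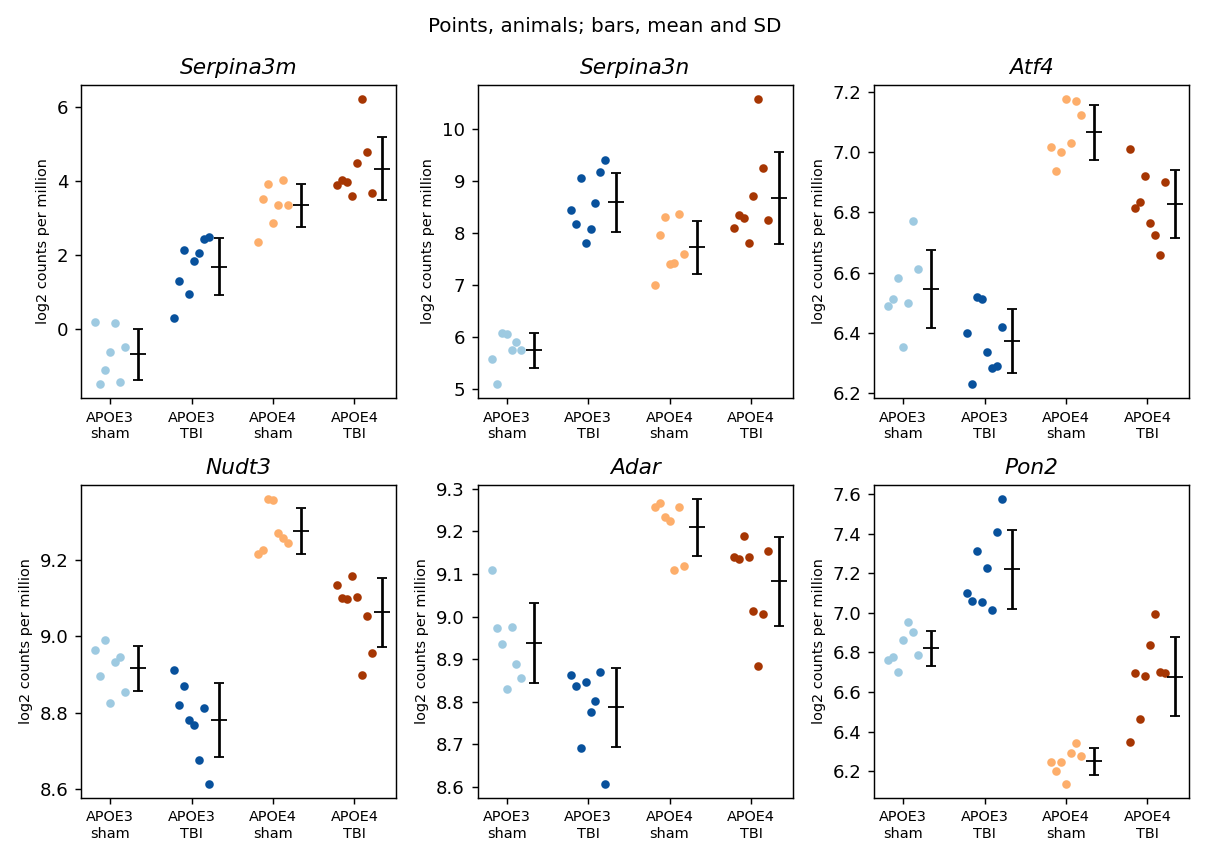
Levels of Serpina3m, Serpina3n, Atf4, Nudt3, Adar and Pon2 in log2 CPM over the listed genes, 1 point per animal by genotype and injury, with group means and SD. Atf4, Nudt3 and Adar are higher and Pon2 is lower in APOE4 mice, by 0.48, 0.31, 0.28 and −0.55 log2 units.

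Trem2 (−0.07 ± 0.12, adjusted p = 0.882), Tyrobp (−0.29 ± 0.14, adjusted p = 0.341) and Apoe (−0.02 ± 0.06, adjusted p = 0.923) did not pass between genotypes. In all 108 genes passed (64 higher, 44 lower in APOE4), and of 31 lists 0 passed with camera and 0 with fry (smallest adjusted p = 0.700 for fry). The Serpina3n call was lost without covariates (0.59, adjusted p = 0.947), by characteristics placement (0.89, adjusted p = 0.108), with limma-voom (0.83, adjusted p = 0.0886), with total counts (0.98, adjusted p = 0.0502), with the depth class (0.99, adjusted p = 0.0547), and in the shallow (1.15, adjusted p = 0.339) and deep libraries alone (0.85, adjusted p = 0.455). It held with DESeq2 (1.09, adjusted p = 0.0083) and with placement by title (1.05, adjusted p = 0.0323). Placing the disputed libraries by title left 56 genes, all among the 108. Without covariates 20 passed, in a model that left out injury too.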

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

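The tests of the library E2073 as an injured animal, of chromosome segments, of ATF4 targets and of splits for the interaction at an unadjusted p were chosen only after the results were seen. Dixon's test was applied to 37 gene levels and list scores in each of the 4 groups, 148 tests in all, and marked 10 values in 8 animals, where chance gives 7.40. Trem2 stood at 4.58 log2 CPM in the APOE3 sham animal D2438, against 4.22 to 4.32 in the other shams of its group. Itgax, an integrin of microglia and dendritic cells, stood at −2.26 log2 CPM in the APOE3 sham D2319 (others −0.52 to 0.66) and at −2.26 in the APOE4 sham E1818 (others −0.36 to 0.27). Both of these are libraries with 0 Itgax counts, whose level is set by the prior count. The cytoskeletal gene Vim stood at 5.49 log2 CPM in the APOE4 sham E1794 (others 5.89 to 6.16). List scores are the mean log2 CPM over list members minus that of the APOE3 shams. The disease-associated microglia score was −0.33 in the APOE3 sham D1956 (others −0.04 to 0.17), and the complement score was −0.45 in the APOE4 sham E1818 (others −0.09 to 0.15). The homeostatic astrocyte score was 0.63 in the APOE3 TBI animal D2439 (others 0.21 to 0.36), 0.17 in the APOE4 sham E1770 (others −0.06 to 0.01) and 0.0896 in the APOE4 TBI animal E1829 (others 0.29 to 0.47). The matrix score was 1.75 in the APOE3 TBI animal D2439 (others 0.37 to 0.88).

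The library E2073, titled as sham and described as TBI, was in no comparison and held Trem2 at 5.23, Tyrobp at 5.24 and Apoe at 6.26 log2 CPM. These exceed the highest shams (4.58, 4.81 and 5.52), and Apoe also exceeds the highest TBI animal (5.76), whereas Gfap (9.43), C3 (1.43), Lcn2 (0.36) and Clec7a (−0.81) lay within the sham range and below the lowest TBI animals (10.50, 6.08, 4.91 and 4.24), as Trem2 and Tyrobp also lay below theirs (5.42 and 5.63). An injured animal with a response the size of the others' is argued against: the slope of its deviation from the sham mean on the injury log2 difference, across genes, was 0.12 (0.1194), against 0.59 to 1.40 in the 16 TBI animals and −0.10 to 0.08 in the 14 shams. Loss of long transcripts in this library may account for its distance, since its deviation fell with transcript length across genes at a rank correlation of −0.648, against −0.312 to 0.197 over the other animals. A mild injury stays open, and the group of this library was not settled.

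In the genotype comparison 1 of 100 splits of the animals, the real one, gave as many genes as the 108 called. The highest other split gave 106, so chance alone rarely gave so many but was not excluded. At an unadjusted p under 0.05 the real split gave 771 genes, and 2 splits, the real one included, gave at least as many, with a highest other of 1343. Long chromosome segments that differ between the mouse lines are argued against as the main source. Of the called genes, 35 had another called gene within 5 Mb, against a median of 46 over 10000 random draws. Scattered loci that act on single genes would not show in this count and stay open. So do the Serpina3 cluster on chromosome 12 and the run of Vps50, Pon2, Asns, Glcci1, Ica1 and Phf14 on chromosome 6. Depth classes were balanced, with 7 shallow and 8 deep libraries in each genotype, so the 92.6% of calls kept with depth class as a covariate was close to fixed and decides nothing. A shared rise of ATF4 targets may or may not accompany Atf4. Of 7 targets already seen among the called genes, Asns (0.24), Bcat1 (0.19), Slc7a5 (0.19), Yars (0.17), Gars (0.15) and Nars (0.13) were higher and Pck2 was lower (−0.28). The 12 targets not yet seen had a median of 0.03, at percentile 87.9 of random lists, which leaves a shared rise undecided.

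For the injury comparisons, 1 of 100 splits, the real one, gave as many genes as the 5053 overall (highest other 2152), the 3799 in APOE3 (highest other 1822) and the 3287 in APOE4 (highest other 2218). The table was selected on this contrast in the same animals, so these splits say nothing about chance. For the injury by genotype interaction, 0 genes were called with edgeR, DESeq2 and limma-voom, a count that all 100 splits meet whatever the data (highest other 0), so it says nothing about chance. At an unadjusted p under 0.05 with edgeR, 85 of 100 splits gave at least the 99 genes of the real one, with a highest other of 728, so chance was not excluded.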

How the results depend on the processing

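Total-count scaling, limma-voom, the depth class, each depth class alone and all settings of the title letter were chosen after seeing the data. Counts are given in the order TBI against sham, within APOE3, within APOE4, APOE4 against APOE3, and F against M, and a comparison left out stayed within 1.5 times its count. An adjusted p under 0.01 gave 2490 (APOE3), 1912 (APOE4), 35 and 315 genes, and one under 0.001 gave 2805, 1357, 737, 17 and 41. An absolute log2 difference of at least 0.58, about 1.5-fold, left 1009, 1087, 913, 6 and 120 genes. A change of at least 2-fold left 457, 519, 430, 2 and 29. Bonferroni gave 1611, 659, 348, 21 and 44, and 1251 for TBI against sham on the p-values of the authors' deposited table. These settings lower counts by construction. Placing the disputed libraries by title gave 56 genes between genotypes, and placing them by characteristics gave 386 for F against M. The cause of these changes was not tested. Without covariates the counts were 20 (APOE4 against APOE3) and 82 (F against M). These models left out injury too, so its effect stayed in the residual variation. All genes called in the main fits kept their sign there, and log2 differences correlated with the main ones at r = 0.986 and 0.996. Fewer animals remained in the shallow libraries alone, which gave 3267, 1758, 1240, 11 and 380 genes, and in the deep libraries alone, which gave 2000 (APOE3), 1040 (APOE4), 6 and 2 (F against M). Leaving out each animal in turn gave 3440 to 3901 genes in APOE3 and 2680 to 3415 in APOE4. Both interactions stayed at 0 genes with edgeR, DESeq2 and limma-voom (99 and 461 genes at an unadjusted p under 0.05 with edgeR). Between 20 and 24 lists passed, the fewest without genes shared between lists. Without genes shared between lists, macrophages (adjusted p = 0.0838) and neuropeptides (0.117) no longer passed, and with the mean-rank permutation test oxidative phosphorylation did not (0.310). Haemoglobin and iron passed among members with an adjusted p under 0.01 (0.0456) and in the mean-rank permutation test (0.000986), as did Alzheimer risk genes in the latter (0.0288). The pseudocount setting planned for normalised values was not run, since the files hold counts. No named gene reversed. The named results that kept their side of the threshold ran from 202 (an absolute log2 difference of at least 0.58) to 279 (no filter on low counts). Genes with few counts limit within-genotype folds.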

Other observations

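The comparison of title letters, its tests, the connectivity ranking and the relation of cholesterol synthesis to neuron genes were chosen after the data were seen. Animals titled F were compared with those titled M over both genotypes and injury states, 15 against 15, and the labels do not spell out the letter. The complement gene C3 was higher in F animals by 1.65 ± 0.32 on the log2 scale (adjusted p = 0.00122), as were the reactive astrocyte genes Steap4 (1.55) and Lcn2 (1.47), the macrophage gene Cd5l (1.55), the lipopolysaccharide-binding protein gene Lbp (1.54) and Wisp2 (1.73). Otof (0.58), Col6a1 (0.68), Myof (0.77), Cfap44 (1.00) and the fatty acid receptor Cd36 (1.19) had the smallest p among the rises. The glutamate receptors Grm2 (−0.58) and Grm4 (−0.48) and Sec14l3 (−0.96), Satb1 (−0.43), Flrt1 (−0.37) and Mapk8 (−0.22) were lower. Tyrobp stood at 0.40 ± 0.14 (adjusted p = 0.0450), a call lost by characteristics placement (0.32, adjusted p = 0.185), without covariates (0.47, adjusted p = 0.460), and in the shallow (0.51, adjusted p = 0.179) and deep libraries alone (0.33, adjusted p = 0.299). Trem2 stood at 0.25 ± 0.12 (adjusted p = 0.149) and Apoe at 0.08 ± 0.06 (adjusted p = 0.390). Among lists tested with fry, haemoglobin clearance and iron (median 0.35, adjusted p = 0.00232), heat shock and oxidative stress (0.12, adjusted p = 0.00793), complement (0.35, adjusted p = 0.0134) and oligodendrocyte precursors (0.19, adjusted p = 0.0142) were higher with the smallest p. Also higher, at an adjusted p from 0.0160 to 0.0486, were Alzheimer risk genes, Fc receptors, Toll-like receptors, macrophages, Trem2-Tyrobp signalling, reactive astrocytes, matrix, homeostatic and disease-associated microglia and lysosome. Oxidative phosphorylation (−0.06, adjusted p = 0.0301), ion channels (−0.08, adjusted p = 0.0486) and cholesterol synthesis (−0.11, adjusted p = 0.0499) were lower. With camera the smallest adjusted p = 0.343 with an estimated correlation, so of 31 lists 17 passed with fry, 19 with camera at a preset correlation and 0 with an estimated one. For complement and reactive astrocytes, the mean scores of F and M animals lay farther apart after TBI (n = 8 each) than in shams (n = 7 each). The reactive astrocyte score was 2.64 ± 0.61 (F) and 2.05 ± 0.38 (M) after TBI, against 0.09 ± 0.15 and 0.01 ± 0.11 in shams, and the complement score 2.13 ± 0.48 and 1.58 ± 0.28, against 0.07 ± 0.11 and −0.10 ± 0.18. The test of this difference did not pass with fry for complement and reactive astrocytes (adjusted p = 0.403 each), chemokines (adjusted p = 0.834) or interferon (adjusted p = 0.896). Chemokines stood at 1.99 (F) and 1.72 (M) after TBI against 0.07 and −0.21 in shams, and the interferon response at 1.56 and 1.61 against 0.07 and 0.05. In all 895 genes passed (541 higher, 354 lower in F), 82 without covariates and 2 in the deep libraries alone. The model without covariates left out injury too. Of 100 splits 1, the real one, gave as many genes, and the highest other gave 156, so chance alone rarely gave so many. Within each genotype all F animals carried higher animal numbers than all M animals. The letter can therefore not be told apart from anything that goes with those numbers, and the splits do not separate them. Column totals over the listed genes also went with the letter. All deep F libraries (4648345 to 6346284 counts) lay below all deep M libraries (6803205 to 8606717). Shallow F libraries (2262242 to 2811624) mostly lay below shallow M libraries (2652839 to 3595246), with some overlap. The depth class as a covariate does not remove differences within a class. The letter can therefore not be told apart from these totals either.

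The test of an injury effect that differs between the letters called 0 genes with edgeR (461 at an unadjusted p under 0.05), DESeq2 (0) and limma-voom (0). Camera at a preset correlation called 19 of 31 lists, 15 of them higher, with lysosome first (median 0.30, adjusted p = 5.20e-10), but 0 passed with an estimated correlation (smallest adjusted p = 0.348) and 0 with fry (smallest adjusted p = 0.190). Of 100 splits 20 gave as many as 461, with a highest other of 1039, so chance was not excluded. Leaving out 1 injured animal titled F gave at the lowest 344 genes, without E2118. The threshold alone would give 269, and the other splits of all animals gave a median of 194. Since other splits often reach such numbers, this decides nothing about a single animal as the source. The interaction with the letter was 0.35 for Trem2 (adjusted p = 0.661) and 0.43 for Tyrobp (adjusted p = 0.631).

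Connectivity was measured among the 444 genes that rose at least 2-fold. It was the mean absolute correlation of each gene with the others across animals, after the means of the 4 groups were removed. Differences between the title letters were not removed, so they can enter the ranks. Tyrobp had rank 5 (0.608) and Trem2 rank 14 (0.588). Both were named as hubs from these samples, so their ranks are not independent evidence.

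The library F1372, titled APOE3 and described as APOE4, was in no comparison. It held Serpina3m at −0.90 log2 CPM, against −1.46 to 2.49 in APOE3 and 2.34 to 6.20 in APOE4 animals, and Serpina3n at 5.81, against 5.10 to 9.40 and 6.99 to 10.57, both inside the APOE3 range only. Atf4 at 7.02 (6.23 to 6.77 in APOE3, 6.66 to 7.17 in APOE4), Nudt3 at 9.35 (8.61 to 8.99, 8.90 to 9.36) and Pon2 at 6.68 (6.70 to 7.58, 6.14 to 6.99) lay inside the APOE4 range only, so its genotype was not settled.

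The placement of the disputed libraries was compared with the authors' deposited table in 3 models. With injury as the only term, the log2 differences had an SD of differences from those of the authors of 0.0037 by title, 0.0609 by characteristics and 0.0383 with both left out. These were 0.014, 0.0604 and 0.0404 with a genotype term, and 0.0201, 0.0611 and 0.0436 with genotype and letter. F1372 is a sham under both placements, so the model without a genotype term does not bear on its genotype.

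Loss of neurons may go with the fall of cholesterol synthesis genes after injury, as a hypothesis found in these data. Cell numbers were not measured. All tested members of both lists (22 excitatory neuron and 17 cholesterol synthesis genes) were lower after injury. A correlation of their scores therefore cannot tell loss of neurons from an injury response that differs in size between animals. Across the 16 TBI animals the cholesterol synthesis score correlated with the excitatory neuron score at Pearson r = 0.652 (permutation p = 0.00582, adjusted p = 0.0233) and Spearman rho = 0.559 (permutation p = 0.0259, adjusted p = 0.0518). Without the 2 animals farthest from the median r was 0.458 (permutation p = 0.0970, n = 14) and rho 0.499 (permutation p = 0.0731, n = 14). Both stayed positive, but passing the threshold rests on those animals, so the hypothesis stays undecided, although the first p met the prediction as written. Within depth classes r was 0.774 (deep) and 0.458 (shallow), within letters 0.759 (F) and 0.395 (M), and within genotypes 0.765 (APOE3) and 0.578 (APOE4), with 8 animals each. The other of 2 relations tested, with the disease-associated microglia score, gave r = −0.46 (permutation p = 0.0725, adjusted p = 0.0966) and rho = −0.43 (permutation p = 0.0992, adjusted p = 0.0992).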
